A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

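RNA of 36 samples was measured on Affymetrix yeast arrays: 3 strains (BY4742 wild-type and its deletions of MSN5 and MTR10) in 2 conditions and 3 kinds of RNA, with 2 arrays in each of 18 groups. Per the labels, cells were grown in synthetic dextrose medium at 30 degrees C to an OD600 of 0.35, split, and resuspended for 30 min in medium with or without amino acids, then given cycloheximide at 100 ug/ml and lysed for gradients of 10 to 50% sucrose. Groups were taken from the labels of the samples.

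The deposited series values are log2 RMA signals, which the authors made with the affy package per the labels; versions of RMA, affy and the scanner software are not given in the sources used here. RMA fits all arrays together and gives every array the same distribution, so that a ratio of pools is relative to the other messages in each pool. A second deposited matrix holds MAS5 signals as intensity on a linear scale, with array means from 553.0 to 607.0. It also holds a detection p-value for each probe set and array, which was used for detection. For an alternative the signals were taken as log2 and each array was centred on its median over the tested genes. Medians over all probe sets before that step differed between pools, with 35.6 and 44.3 in fed wild-type polysome and 93.9 and 94.2 in non-polysome RNA. The direction of a ratio in MAS5 signals may therefore depend on it. The series values cover 5684 of the 10928 probe sets of that matrix, 99.8% of them called Present across arrays at a detection p-value of 0.05, against 6.8% of the other 5244, which were not used. The series values run from 3.42 to 14.61. The columns of the MAS5 matrix were matched to the RMA arrays by correlation of values centred on each gene's mean, and 2 of them matched an array of another group than the one they name.

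Of the 5684 probe sets, 93 are controls and 212 others have no gene; 5379 have 1 gene. The annotation's Entrez numbers gave current symbols, 12 of them updated. For 39 genes with several probe sets the one with the highest mean was kept, which left 5338 genes. A filter that asks for Present calls on both arrays of at least 1 group removed 0 genes, and 5276 genes were Present on all 36 arrays. Folds of genes not called Present in the dimmer group are lower bounds, for which signals under the lowest Present signal of the array were set to that signal (3.64 to 5.62 on the log2 scale).

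A linear model with a mean for each of the 18 groups was fitted to all genes with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided), with 18 residual and 3.92 prior degrees of freedom. In each of 19 comparisons p-values were adjusted by Benjamini and Hochberg over the 5338 genes, and a gene was called at an adjusted p under 0.05. The comparisons were the response of total RNA to starvation in each strain, each mutant against wild-type in fed and in starved total RNA, polysome against non-polysome RNA in fed wild-type, the change of that ratio on starvation in each strain, the ratio of each mutant against wild-type in each condition, and the differences of the starvation changes between each mutant and wild-type.

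Gene lists (35, of which 1 had no measured member) were written from textbook knowledge before the data were examined, as were the groups, the comparisons, the alternatives and the rule for named genes. Lists were tested with camera (limma) with a preset correlation between genes of 0.01 and, as an alternative, with an estimated correlation, adjusted over all 646 tests of 34 lists in 19 comparisons. Counts adjusted over the list alone use Benjamini and Hochberg within the list. Named genes are the deleted and marker genes, GCN4 and CPA1 in every comparison, the 6 with the largest change in each direction (3 in the other comparisons) among called genes that passed a rule on single arrays, and up to 4 members with the smallest p of a list that is described. In comparisons of 2 groups the arrays must not overlap between them, which chance gives in 33.3% of genes for 2 arrays against 2. In comparisons of more groups both differences formed by replicate number must have the sign of the estimate. That is a weaker rule, and the numbers do not pair the samples throughout.

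The overlap of both mutants' differences was set against lists drawn independently and against 100 simulated data sets without changes that share the wild-type arrays. The fit was tested on simulated data with 50 changed genes of each size. In the total RNA comparison it recovered 58% of genes changed by 0.5, 92% by 1 and 98% by 2 on the log2 scale, with 5 false calls, and in the comparison of ratio changes in wild-type 26%, 72% and 92%, with 8 false calls. Of 3 lists shifted by 0.5 all 3 were called and 0 others. Noise was drawn for each gene independently there, so false list calls from genes that vary together were not tested. Gene length trends were taken with lowess (span 0.3), errors of list medians in the closing part from the spread of the median between replicate arrays, pooled over the 18 groups, and figures drawn with matplotlib 3.10.9 under Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A measure of RNA integrity is the mean difference between 3-prime and 5-prime probe sets of 6 control genes.

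The alternatives were the MAS5 signals, arrays centred on their median, no detection filter, genes Present on all 36 arrays, a fit with the compared groups alone, eBayes with trend and robust settings, a block for the replicate number, total RNA in place of non-polysome RNA as the denominator, and each array left out in turn. Total RNA holds the polysome pool too, so a ratio to it sets a part against the whole and can change less for that reason. Added after the data were seen were the MAS5 signals without the 2 mismatched columns and a block with crossed replicate numbers. Cultures were split, and fed and starved total RNA arrays of the same number deviated together from their group means in each strain (correlation across genes 0.18 in wild-type, 0.28 in msn5, 0.24 in mtr10), so that the block is given beside those responses where it moves them. Scan dates were not used here.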

Results

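Transcript levels were measured on 36 Affymetrix yeast arrays in Saccharomyces cerevisiae. The strains were the MATalpha laboratory strain BY4742 (wild-type) and its deletions of MSN5 and of MTR10, which encode carriers that move cargo, tRNA included, through the nuclear pore. Cultures were split and kept for 30 min in synthetic medium with amino acids (fed) or without them (starved), then treated with cycloheximide, which holds ribosomes on messages. Sucrose gradients gave a polysome pool, whose messages carry several ribosomes, and a non-polysome pool, and total RNA was measured beside them. The 3 strains, 2 conditions and 3 kinds of RNA made 18 groups of 2 arrays, a number that limits the precision of every value. Levels below are log2 means ± SD (n = 2), changes are log2 differences ± the standard error of the fit, and 5338 genes were tested in each of 19 comparisons.

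The deleted genes were read in every sample. MSN5 (YDR335W) measured 11.26 ± 0.04 in fed wild-type and 4.16 ± 0.14 in fed msn5 total RNA, at least 88.1-fold lower, where "at least" means that an undetected signal was replaced by the lowest signal called Present on the same array. In starved total RNA it measured 11.73 ± 0.28 in wild-type and 3.82 ± 0.17 in msn5, at least 112-fold lower. MTR10 (YOR160W) measured 11.04 ± 0.07 in fed wild-type and 3.98 in both fed mtr10 total RNA arrays, at least 45.8-fold lower, and 10.49 ± 0.01 against 3.97 ± 0.42 after starvation, at least 41.9-fold lower. Each gene stayed high in the strain deleted for the other, with group means of MSN5 from 11.57 to 12.57 in mtr10 and of MTR10 from 10.12 to 10.78 in msn5. The fed non-polysome arrays of both mutants stood apart. MSN5 read 6.85 and 7.23 there in msn5, against 3.64 to 4.75 on the other 10 arrays of that strain, and MTR10 read 5.48 and 5.17 in mtr10, against 3.64 to 4.67 on the other 10. PHO84, a phosphate transporter gene that is high in msn5, read 7.74 and 10.92 on these mtr10 arrays, against 7.27 to 8.58 on the other 10 of that strain, while PHO5 of the same regulon read 8.61 and 8.85. HIS3 is deleted only in part in BY4742, and its probe set gave signal in every group, so it checks nothing.

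**Figure D1:**
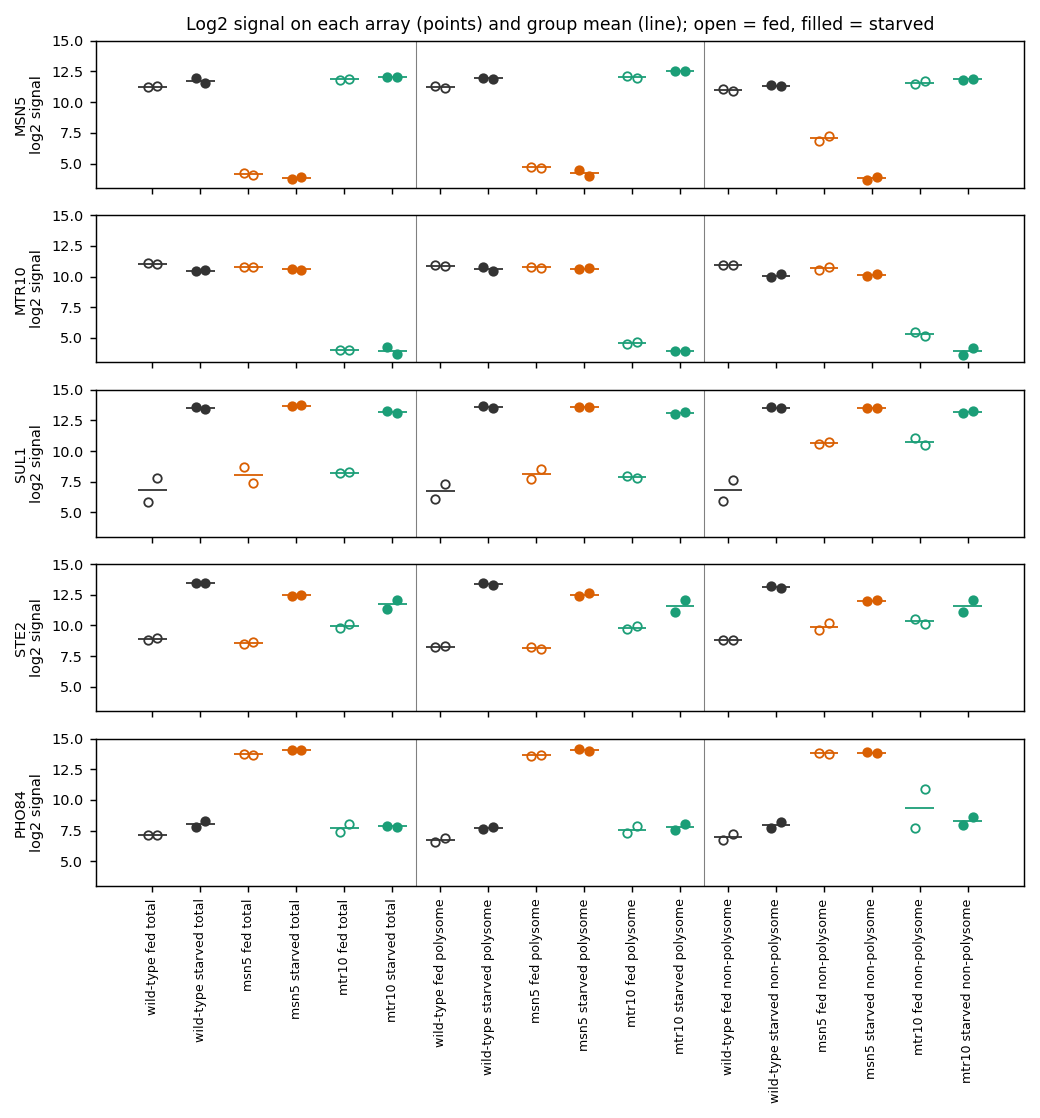
Log2 signal of MSN5, MTR10, SUL1, STE2 and PHO84 on each of the 36 arrays, by group, with open symbols for fed and filled symbols for starved cultures. MSN5 is low in the msn5 strain, MTR10 in the mtr10 strain, and PHO84 is high in msn5.

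The first comparison asks how wild-type messages change when amino acids are withdrawn. SUL1, a sulfate permease, rose by 6.69 ± 0.50 in total RNA (from 6.82 ± 1.33 to 13.51 ± 0.13; 5.74 without wild-type fed replicate 1 and 7.63 without fed replicate 2), and SEO1, a putative permease, rose 42.8-fold (5.42 ± 0.27). The carnitine transporter gene CRC1 rose 23.3-fold. The largest falls were of HO, the mating-type switching endonuclease (8.36-fold, -3.06 ± 0.24), CLB6, an S-phase cyclin (7.47-fold), URA1, a pyrimidine enzyme (6.44-fold), LTV1 and NIP7, ribosome assembly factors (6.06-fold and 5.57-fold), and TAT1, an amino acid permease (5.54-fold). LTV1 gave -1.96 without starved replicate 1 and -3.24 without starved replicate 2. In all, 3429 genes changed by limma, 1678 upward and 1751 downward, and 507 rose and 450 fell at least 2-fold.

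All 8 arginine genes (8 adjusted over the list alone) and all 27 genes of sulfur assimilation and methionine synthesis (27 adjusted over the list alone) rose, with medians of 2.20 and 2.48. ARG7 rose 6.07-fold (2.60 ± 0.12), ARG8 4.20-fold, MET16, which reduces activated sulfate, 10.9-fold (3.44 ± 0.25), and MET1 6.93-fold. Of 8 lysine genes 7 rose, LYS1 by 5.54-fold, and all 11 branched-chain genes rose, LEU4 by 1.00. Of 6 histidine genes 5 rose and 1 fell, of 13 aromatic genes 10 rose and 1 fell, and of 24 genes of other amino acids 15 rose and 6 fell. HIS4 rose 3.34-fold and TRP4 rose by 1.62. These counts stood unchanged adjusted over the list alone, and the medians were 0.89 (lysine), 0.48 (branched-chain), 1.07 (histidine), 0.58 (aromatic) and 0.47 (other). None of these 7 lists was called with an estimated correlation, with adjusted p = 0.225 (arginine), 0.501 (sulfur), 0.636 (lysine), 0.682 (branched-chain), 0.688 (histidine), 0.628 (aromatic) and 0.697 (other).

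CPA1, a subunit of the enzyme that makes carbamoyl phosphate for arginine, whose message carries an upstream reading frame, rose 2.80-fold (1.48 ± 0.10), and HIS3 rose 2.02-fold. GCN4, the activator of amino acid genes, whose translation is set by upstream reading frames, rose by 0.27 ± 0.10, from 13.20 to 13.47. The GCN4 call ended without any one of the 4 arrays (adjusted p from 0.0558 to 0.104), and in the MAS5 signals without their 2 mismatched columns it turned to -0.19. MSN5 rose by 0.47, but only 0.27 (adjusted p = 0.203) without wild-type starved total RNA replicate 1, and its call also ended without wild-type fed total RNA replicate 1 (adjusted p = 0.0557). MTR10 fell by 0.55, a call that ended in the MAS5 signals without those columns (adjusted p = 0.335), as did those of LEU4, ILV2, OAC1 and LEU9 among the branched-chain genes, ILV2 with adjusted p = 0.244. As deposited, the MAS5 signals gave 0 calls by limma and 27 genes at an unadjusted p under 0.05, since the columns of wild-type fed and starved total RNA marked a match the arrays of the other condition (correlation across genes 0.96 and 0.95, and -0.42 and -0.32 with their own). Without both columns 2553 genes were called.

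Of 118 ribosome biogenesis genes 116 fell (117 adjusted over the list alone), with a median of -1.51, and all 19 RNA polymerase I and III genes fell (19 adjusted over the list alone), with a median of -1.39. RRP15 fell by 1.68, MPP10 by 1.86 and RPC31 by 2.29. Of 127 cytosolic ribosomal protein genes 72 fell (68 adjusted over the list alone), with a median of -0.35, RPL12A by 1.07. Of 33 translation factor genes 31 fell, TIF5 by 1.43, of 20 aminoacyl-tRNA synthetase genes 11 fell, and of 22 genes of tRNA processing and nuclear transport 15 fell, among them SEN34, a subunit of the tRNA splicing endonuclease, by 1.72. The same numbers of the last 3 lists fell adjusted over the list alone, with medians of -0.66, -0.27 and -0.60. Of 66 mitochondrial ribosomal protein genes 46 fell and 2 rose (46 and 2 adjusted over the list alone), with a median of -0.43. The adjusted p with an estimated correlation was 0.688 (biogenesis), 0.653 (polymerases), 0.881 (ribosomal proteins), 0.356 (factors), 0.837 (synthetases), 0.355 (tRNA) and 0.712 (mitochondrial), so none of these list calls held.

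Stress, cell cycle and mating genes changed as well. Of 41 general stress genes 34 rose and 2 fell (36 and 2 adjusted over the list alone), with a median of 0.93, and the glycogen synthase gene GSY1 rose 7.78-fold. Of 22 genes under nitrogen catabolite repression 17 rose and 1 fell (17 and 1 adjusted over the list alone), with DUR3, a urea transporter, up 4.14-fold. Of 26 chaperone genes 18 fell and 3 rose, of 34 proteasome genes 31 fell and 1 rose, and of 24 G1/S genes 17 fell, counts that stood unchanged adjusted over the list alone. HSP82 fell by 2.25, PRE9 by 0.93 and the ribonucleotide reductase gene RNR1 by 2.23. Of 27 iron genes 14 rose (13 adjusted over the list alone), and of 11 purine genes 7 rose (7 adjusted over the list alone). All 7 genes that are normally expressed in MATa cells only rose (7 adjusted over the list alone) in this MATalpha strain, with a median of 4.20: MFA2, an a-factor gene, rose 34.9-fold, AGA2, an agglutinin subunit, 25.7-fold, STE2, the alpha-factor receptor, 23.8-fold (from 8.88 ± 0.11 to 13.45 ± 0.04), and BAR1, a protease, 18.4-fold. The 5 MATalpha-specific genes had a median of -0.13, with 1 up and 1 down (adjusted p = 0.716). These list calls rest on the preset correlation, since the adjusted p with an estimated correlation was 0.726 (stress), 0.315 (nitrogen), 0.501 (chaperones and G1/S), 0.178 (proteasome), 0.871 (iron), 0.619 (purine) and 0.325 (MATa).

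**Figure D2:**
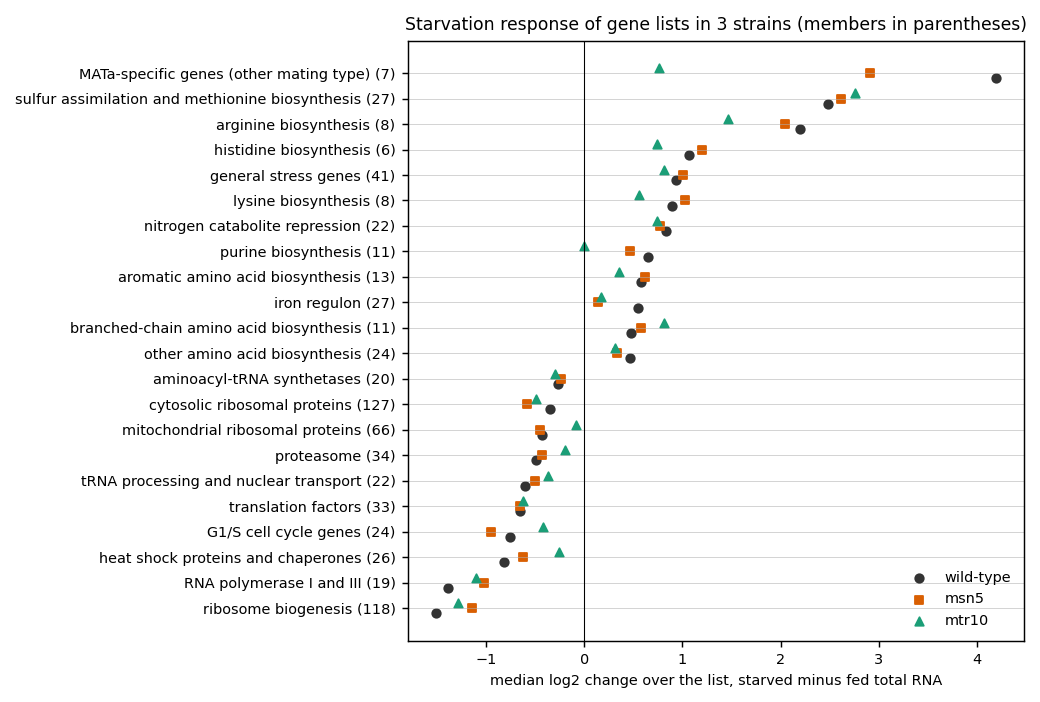
Median log2 change of total RNA on starvation over each of 22 gene lists (horizontal axis), in the 3 strains. Sulfur and arginine lists lie highest among the biosynthesis lists and ribosome biogenesis lies lowest in wild-type at -1.51.

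Both mutants responded to starvation with most of the same genes. In msn5 3258 genes changed (1540 up, 1718 down) and in mtr10 2599 (1323 up, 1276 down). Across the 5338 genes, which are not independent replicates, the changes correlated with those of wild-type at 0.94 in msn5 and 0.84 in mtr10, and 2862 and 2135 genes were called in the same direction as in wild-type. SUL1 rose 50.1-fold in msn5 (78.6-fold and 31.9-fold without msn5 fed total RNA replicate 1 and 2) and 30.2-fold in mtr10, SEO1 rose 51.4-fold in msn5, MET28, a regulator of sulfur genes, rose 24.8-fold and 21.9-fold, and MET2 rose 17.6-fold in mtr10. The alpha-factor gene MF(ALPHA)2 fell 21.4-fold in msn5 (from 12.07 ± 0.25 to 7.65 ± 0.29), TAT1 fell 8.83-fold and HO 8.79-fold there, and in mtr10 KRE33, a ribosomal RNA acetyltransferase, fell 5.03-fold, the phosphatase gene PHO3 4.84-fold and RPA43 4.80-fold. CPA1 rose 3.15-fold in msn5 and 2.55-fold in mtr10. GCN4 rose by 0.34 and 0.37. Those GCN4 calls ended without msn5 starved total RNA replicate 2 (adjusted p = 0.0553) and mtr10 fed total RNA replicate 2 (0.21, adjusted p = 0.142), and in the MAS5 signals GCN4 turned to -0.20 in msn5 and -0.05 in mtr10, where 1683 genes were called.

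By list, all 8 arginine genes rose in both mutants (8 adjusted over the list alone in each), with medians of 2.05 in msn5 and 1.46 in mtr10, and 27 and 26 of 27 sulfur genes rose (27 and 26 adjusted over the list alone), with medians of 2.62 and 2.76. Lysine genes rose in 7 and 5 of 8, histidine genes in 5 and 4 of 6, branched-chain genes in 9 and 10 of 11, with the same counts adjusted over the list alone. Of 13 aromatic genes 11 and 8 rose and 1 fell in each, and of 24 other amino acid genes 15 and 14 rose and 5 fell in each, also adjusted over the list alone. Of the 118 ribosome biogenesis genes 113 fell in msn5 and 117 in mtr10 (115 and 117 adjusted over the list alone), and of the 127 ribosomal protein genes 118 and 98 fell (119 and 104 adjusted over the list alone). All 7 MATa-specific genes rose in msn5 (7 adjusted over the list alone), with a median of 2.91, and 4 of 7 in mtr10 (4 adjusted over the list alone), median 0.76, where the list was not called (adjusted p = 0.0950). Of the 5 MATalpha-specific genes 4 fell in each mutant (4 adjusted over the list alone), with medians of -0.57 and -0.59. None held with an estimated correlation, where adjusted p = 0.178 (arginine in both, MATalpha in msn5), 0.325 and 0.315 (sulfur), 0.531 and 0.712 (lysine), 0.531 and 0.688 (histidine), 0.604 and 0.324 (branched-chain), 0.574 and 0.703 (aromatic), 0.688 and 0.697 (other), 0.714 and 0.646 (biogenesis), 0.750 and 0.737 (ribosomal proteins), 0.355 (MATa) and 0.219 (MATalpha in mtr10).

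**Figure D3:**
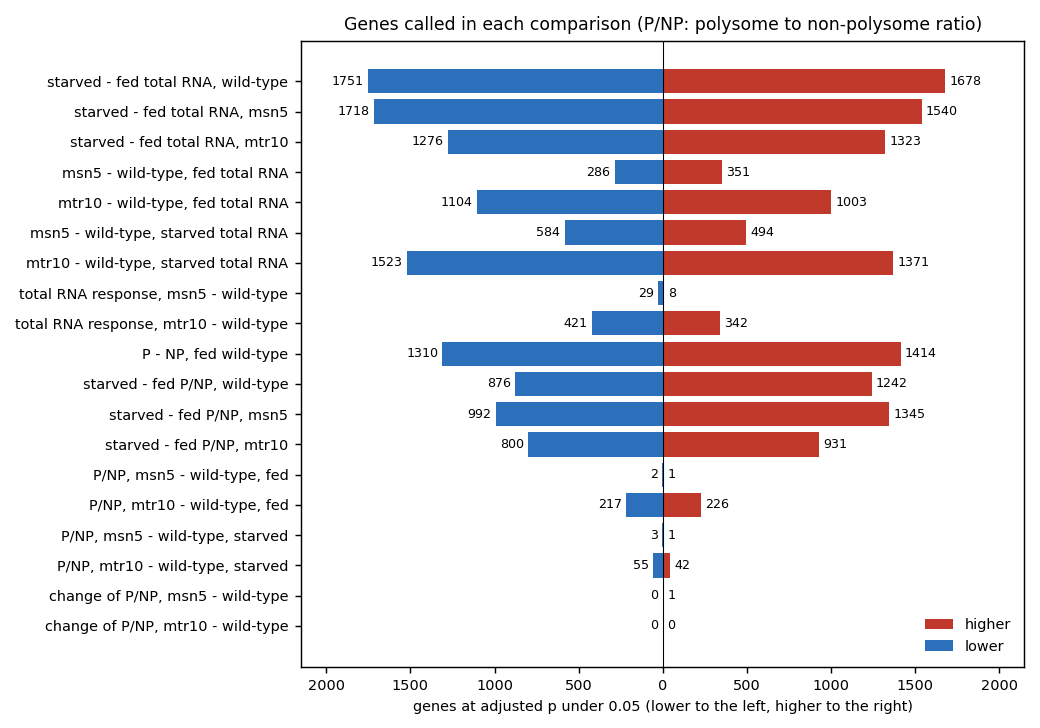
Number of genes called higher and lower in each of the 19 comparisons (bars to either side of 0). Wild-type starvation gives 1678 higher and 1751 lower, and the differences of the ratio change between strains give 1 and 0.

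Fed msn5 cells differed from fed wild-type first in phosphate and mating genes. PHO84, the high-affinity phosphate transporter, was 94.9-fold higher (6.57 ± 0.54, 13.71 ± 0.08 against 7.14 ± 0.05), SPL2, which acts on low-affinity phosphate transport, 36.3-fold, the transporter gene PHO89 6.81-fold, the acid phosphatase genes PHO11 and PHO5 6.05-fold and 5.08-fold, and PHM6 5.23-fold. Of 17 phosphate regulon genes 15 were higher and 1 lower (16 and 1 adjusted over the list alone), with a median of 1.17 and an adjusted p of 0.0132 with an estimated correlation. Beside MSN5 itself the lowest were HUG1, a checkpoint gene (5.37-fold), the pheromone-induced genes PRM1 (4.76-fold), FIG1 (4.63-fold) and PRM6 (4.10-fold), and the cell wall gene DAN1 (4.36-fold). Of 14 pheromone response genes 12 were lower (12 adjusted over the list alone), FUS1 with -1.79 and FAR1 with -1.04, median -0.90. Of the 5 MATalpha-specific genes 4 were lower (5 adjusted over the list alone), STE3, the a-factor receptor, with -0.94, median -0.94. Both lists held with an estimated correlation (adjusted p = 0.00855 and 0.00497). In all 637 genes differed, 351 higher and 286 lower, and this count depends on single arrays: it lay between 238 and 346 with each of the 4 arrays left out, lowest without wild-type fed total RNA replicate 1, 342 in the MAS5 signals without the mismatched columns, and 1530 with only the compared groups in the fit.

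Other lists of fed msn5 were called with the preset correlation only. Of 41 general stress genes 18 were higher (25 adjusted over the list alone), DCS2 with 1.40, and of 22 genes under nitrogen catabolite repression 8 were higher (12 adjusted over the list alone), with adjusted p = 0.574 and 0.325 with an estimated correlation. Of 24 G1/S genes 12 were lower (13 lower and 2 higher adjusted over the list alone), the cyclin gene CLN1 with -1.07, and of 27 sulfur genes 11 were lower (15 lower and 2 higher adjusted over the list alone), with adjusted p = 0.504 and 0.726 with an estimated correlation. Among the sulfur genes STR3, MUP1 and MHT1 lost their calls without wild-type fed total RNA replicate 2, STR3 moving from -1.31 to -0.79 (adjusted p = 0.0922) and MHT1 from -0.99 to -0.62. Of 118 ribosome biogenesis genes 1 was lower (0 adjusted over the list alone), with a median of -0.28 (adjusted p = 0.878 with an estimated correlation). The amino acid lists other than sulfur were not called. Median, mean and test differed in sign for lysine (median -0.03, mean 0.04) and aromatic genes (median -0.01, mean 0.04, test down). GCN4 and CPA1 gave -0.10 and -0.13 (adjusted p = 0.623 and 0.434).

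Fed mtr10 cells differed at 2107 genes, 1003 higher and 1104 lower, while the MAS5 signals without the mismatched columns gave 863 higher and 629 lower. The highest included the MATa-specific genes AGA2 (12.9-fold, 3.69 ± 0.31), MFA1 (12-fold) and MFA2 (9.57-fold), the glycerol transporter gene STL1 (9.43-fold), ARO10, of amino acid catabolism (7.95-fold), and SRT1, of dolichol synthesis (6.35-fold). All 7 MATa-specific genes were higher (7 adjusted over the list alone), median 1.60. After MTR10 the lowest were QDR2, a multidrug transporter (16.9-fold, -4.08 ± 0.23), the cytosine permease homologue FCY21 (8.85-fold), BDH2 (6.50-fold), PNS1 (5.48-fold) and FIT3, a cell wall protein of iron uptake (3.75-fold). Of 27 iron genes 16 were lower and 1 higher (16 and 2 adjusted over the list alone), the siderophore transporter gene ARN1 with -1.47. Of 22 genes under nitrogen catabolite repression 14 were higher and 3 lower (14 and 3 adjusted over the list alone), PUT1, of proline use, with 1.56, and of 11 purine genes 8 were higher (9 adjusted over the list alone), ADE17 with 0.91. Of 8 lysine genes 5 were higher and 1 lower (5 and 1 adjusted over the list alone), LYS20 with 1.63, and of 11 branched-chain genes 8 were lower and 1 higher (9 and 1 adjusted over the list alone), OAC1 with -1.02. Of 14 pheromone genes 5 were higher and 1 lower (7 and 1 adjusted over the list alone). None held with an estimated correlation, where the adjusted p was 0.325 (MATa), 0.766 (iron), 0.504 (nitrogen), 0.355 (purine), 0.712 (lysine) and 0.688 (branched-chain and pheromone).

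Arginine, sulfur, histidine, aromatic and other amino acid genes of fed mtr10 were not called as lists, nor were ribosomal protein genes (0 higher, 6 lower, and 3 lower adjusted over the list alone) and ribosome biogenesis genes (5 higher, 1 lower, and 4 and 1 adjusted over the list alone). The aromatic list had a median of 0.00 and a mean of 0.19. GCN4 and CPA1 gave -0.13 and -0.02 (adjusted p = 0.334 and 0.914), and MSN5 was higher by 0.61. The count was 1384 without wild-type fed total RNA replicate 1. The mean 3-prime minus 5-prime signal of 6 control genes, a measure of RNA integrity, was 1.35 ± 0.12 in fed wild-type, 1.64 ± 0.05 in fed msn5 and 1.74 ± 0.07 in fed mtr10 total RNA.

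The 2 fed mutants shared 118 genes higher and 118 lower than wild-type, against 65.9 and 58.9 for independent lists, and 102 went opposite ways. Both differences use the same wild-type arrays. Simulated data without true changes gave a correlation across genes of 0.5 from this alone and a covariance of 0.013, against 0.21 and 0.037 measured. They gave 0 shared calls, which the absence of changes all but fixed in advance. What the shared controls add where genes do change was not simulated, so part of the excess may come from them. The share of genes with the same sign was 59.9% against 66.7% simulated. Such values of noise alone are no benchmark for genes of which many change. After starvation 258 genes were higher and 330 lower in both and 150 went opposite ways, against 127 and 166 for independent lists, with a covariance of 0.088 against 0.013. Its correlation of 0.36 against 0.5 and same-sign share of 64.5% against 66.8% lay below the simulated values, and the shared wild-type arrays bear on these counts too. Leaving out single arrays moved the fed overlap between 67 genes (without wild-type fed total RNA replicate 1) and 187 (without mtr10 fed total RNA replicate 1).

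In starved total RNA msn5 again had higher PHO84 (64.8-fold, 6.02 ± 0.54), SPL2 (21.5-fold) and PHO89 (16.6-fold), and lower MF(ALPHA)2 (25.1-fold, 7.65 ± 0.29 against 12.30 ± 0.20) and PCL1, a G1 cyclin (9.68-fold). Of 17 phosphate genes 14 were higher and 1 lower (15 and 1 adjusted over the list alone; adjusted p = 0.0645 with an estimated correlation). Of 14 pheromone genes 13 were lower (14 adjusted over the list alone), FUS1 with -2.13, and all 5 MATalpha-specific genes were lower (5 adjusted over the list alone), median -1.49; both lists held with an estimated correlation (adjusted p = 0.00855 and 0.000201). Of the 7 MATa-specific genes 6 were lower (7 adjusted over the list alone), BAR1 with -2.39, and of 24 G1/S genes 13 were lower (14 adjusted over the list alone), with adjusted p = 0.325 for both with an estimated correlation. Of 26 chaperone genes 10 were higher (12 adjusted over the list alone), SSA1 with 1.35, and of 41 stress genes 14 were higher (17 adjusted over the list alone), with adjusted p = 0.538 and 0.726 with an estimated correlation. Of 127 ribosomal protein genes 12 were lower (4 adjusted over the list alone; adjusted p = 0.851 with an estimated correlation). The amino acid lists were not called: sulfur genes had a median of -0.01 and a mean of 0.00, aromatic genes -0.06 and 0.00, and other genes -0.01 and 0.04. In all 1078 genes differed (494 higher, 584 lower), 417 without msn5 starved total RNA replicate 2 and 433 in the MAS5 signals without the mismatched columns, and 319 with only the compared groups in the fit. The 3-prime minus 5-prime signal was 1.77 ± 0.11 in starved msn5 total RNA against 1.31 ± 0.07 in starved wild-type.

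Starved mtr10 differed from starved wild-type at 2894 genes, 1371 higher and 1523 lower, while the MAS5 signals without the mismatched columns gave 1038 higher and 947 lower. CSN9, a signalosome subunit, was 8.59-fold higher, STL1 5.41-fold and the Golgi gene BUG1 4.29-fold. GTO3, a glutathione transferase, was 11.9-fold lower and FCY21 7.60-fold. Of 27 iron genes 20 were lower and 1 higher (20 and 1 adjusted over the list alone), the iron permease gene FTR1 with -2.04, median -1.10. Of 26 chaperone genes 19 were higher and 1 lower (19 and 1 adjusted over the list alone), HSP82 with 1.62, and of 34 proteasome genes 21 were higher and 2 lower (21 and 2 adjusted over the list alone), RPT2 with 1.62. Of 118 ribosome biogenesis genes 36 were higher and 2 lower (33 and 1 adjusted over the list alone), a list whose median of 0.27 turned to -0.07 in the MAS5 signals without the mismatched columns. Of 127 ribosomal protein genes 42 were lower and 6 higher (38 and 5 adjusted over the list alone), and of 8 arginine genes 5 were lower (5 adjusted over the list alone), median -0.51. Of the 7 MATa-specific genes 5 were lower (5 adjusted over the list alone). None of these lists held with an estimated correlation, where the adjusted p was 0.712 (iron and MATa), 0.355 (chaperones and proteasome), 0.934 (biogenesis), 0.940 (ribosomal proteins) and 0.732 (arginine). As deposited, the MAS5 signals gave 1623 calls. The 6 other amino acid lists were not called; sulfur genes had a median of -0.09 with the test upward, and branched-chain genes a median of 0.04 and a mean of -0.06. The 3-prime minus 5-prime signal was 2.08 ± 0.06 in starved mtr10 total RNA against 1.31 ± 0.07 in starved wild-type.

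The test of the difference between strains in the response to starvation asks which changes depend on each carrier. In msn5 37 genes differed, 8 with a larger rise or smaller fall and 29 the other way, and 501 passed an unadjusted p of 0.05. With a block for the replicate number 90 genes differed (27 and 63), STE3, SAG1 and HSP82 gaining their calls, and no list call changed. MF(ALPHA)2 gave -3.16 ± 0.27, BAR1 -2.62 ± 0.33 and PCL1 -2.17 ± 0.28. The 5 MATalpha-specific genes held 2 such genes (5 adjusted over the list alone), with a median of -0.55 and an adjusted p of 0.000201 with an estimated correlation. The 7 MATa-specific genes held 2 (5 adjusted over the list alone), median -1.13, and chaperone genes 2 the other way (13 adjusted over the list alone), median 0.43, with adjusted p = 0.178 for both with an estimated correlation. SSA1 (1.29 ± 0.26), CSR2 (0.98) and RIO1 (0.95) led upward, but without the mismatched columns their MAS5 adjusted p was 0.281, 0.441 and 0.438, and SSA1 lost its call without wild-type fed replicate 2 (adjusted p = 0.144), wild-type starved replicate 2 (0.0505), msn5 fed replicate 1 (0.147) or msn5 starved replicate 2 (0.106) of total RNA. GCN4 (0.08, adjusted p = 0.949) and CPA1 (0.17, adjusted p = 0.792) did not pass, nor did any of the amino acid lists but sulfur (median 0.39, 0 genes, 2 adjusted over the list alone; adjusted p = 0.691 with an estimated correlation). Lysine (median 0.02), aromatic (0.00) and other genes (0.02) differed in sign between median, mean and test. The count was 15 without wild-type fed total RNA replicate 2, 57 without wild-type starved total RNA replicate 2, and 7 with only the compared groups in the fit.

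In mtr10 763 genes differed in their response, 342 upward and 421 downward. The MATa-specific rise was smaller: AGA2 gave -4.18 ± 0.43, MFA2 -4.08 ± 0.46 and ASG7 -3.87 ± 0.28, and all 7 members passed (7 adjusted over the list alone), median -3.67. The fed level in mtr10 was already raised. AGA2 went from 10.27 ± 0.07 to 10.77 ± 0.57 there and from 6.58 ± 0.47 to 11.26 ± 0.14 in wild-type. ASG7 went from 8.46 ± 0.30 to 8.21 ± 0.34 in mtr10 and from 7.18 ± 0.40 to 10.81 ± 0.10 in wild-type. Of 14 pheromone genes 9 were lower (10 adjusted over the list alone), PRM1 with -1.93. HO (2.27 ± 0.34), SSA1 (2.16 ± 0.26) and FMP48 (1.89 ± 0.38) led upward, FMP48 losing its call in the MAS5 signals without the mismatched columns (adjusted p = 0.0811). Of 26 chaperone genes 16 were higher (19 adjusted over the list alone), and of 34 proteasome genes 12 (17 adjusted over the list alone). Of 8 arginine genes 5 rose less (6 adjusted over the list alone), median -0.59, as did 4 of 8 lysine (4 adjusted over the list alone) and 3 of 13 aromatic genes (3 adjusted over the list alone), while 3 of 11 branched-chain genes were higher (5 adjusted over the list alone). ARG1 gave -1.31 and ARG3 -1.55. In the MAS5 signals without those columns ARG7, ARG3 and ARG8 lost their calls, ARG8 with adjusted p = 0.289. ARG3 gave -1.23 without mtr10 fed total RNA replicate 1 (adjusted p = 0.0596). The adjusted p with an estimated correlation was 0.0623 (MATa), 0.141 (pheromone), 0.178 (chaperones and proteasome), 0.439 (arginine), 0.688 (lysine) and 0.712 (aromatic and branched-chain), so none held. Ribosomal protein genes (1 higher, 2 lower, 0 adjusted over the list alone, median -0.14) and biogenesis genes (2 higher, 0 adjusted over the list alone, median 0.24) were called with adjusted p = 0.934 and 0.943 with an estimated correlation, and the biogenesis median turned to -0.12 in the MAS5 signals without those columns. GCN4 (0.10) and CPA1 (-0.13) did not pass (adjusted p = 0.695 and 0.568). Other amino acid genes had a median of 0.00 and a mean of -0.14. The count was 443 without mtr10 starved total RNA replicate 2 and 264 in the MAS5 signals without those columns (85 upward, 179 downward). The 3-prime minus 5-prime signal went from 1.74 ± 0.07 to 2.08 ± 0.06 in mtr10 and from 1.35 ± 0.12 to 1.31 ± 0.07 in wild-type.

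In fed wild-type the polysome and non-polysome pools differed at 2724 genes, 1414 higher in polysomes and 1310 lower. Every array was scaled to the same distribution, so these ratios are relative to the other messages of the pool. Total RNA, the alternative denominator, holds the polysome pool as well, so a ratio to it is another measure that can differ less. The cell wall genes DAN4 (5.66-fold), FLO11 (4.59-fold), FIG2 (3.86-fold) and TIR3 (3.74-fold), the chaperone gene HSP26 (3.86-fold) and HBN1 (3.65-fold) led in polysomes. HXT14 (9.99-fold, -3.32 ± 0.24), the spore gene GAS4 (6.52-fold), ADA2, a transcription coactivator (5.76-fold), the meiotic splicing factor gene MER1 (5.71-fold), HAC1, whose unspliced message is held from translation (5.29-fold, -2.40 ± 0.71), and RRT15 (4.81-fold) led in the non-polysome pool. GCN4 gave -0.46 and CPA1 -0.34, both toward the non-polysome pool. With total RNA as the denominator 670 genes were called, and DAN4 (-0.52), FLO11 (-0.49) and FIG2 (-0.75) turned, while HSP26 (0.72), TIR3 (0.18), HAC1 (-1.86), RRT15 (-0.78), GCN4 (-0.15) and CPA1 (-0.07) lost their calls. HAC1 moved to -3.27 without wild-type fed polysome replicate 2 and to -1.53 (adjusted p = 0.152) without replicate 1, on which CPA1 also lost its call (adjusted p = 0.051), as it did without non-polysome replicate 2 (adjusted p = 0.0654).

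By list, 21 of 34 proteasome genes were higher in polysomes and 2 lower (23 and 2 adjusted over the list alone), RPN7 with 0.83, and 21 of 43 respiration genes were higher and 2 lower (21 and 2 adjusted over the list alone), LSC2 with 1.57. Chaperone genes gave 13 of 26 higher and 1 lower (14 and 1 adjusted over the list alone), AHA1 with 1.22, synthetase genes 11 of 20 higher (11 adjusted over the list alone) and ergosterol genes 12 of 23 higher and 2 lower (12 and 2 adjusted over the list alone). Of genes under nitrogen catabolite repression 9 of 22 were lower and 2 higher (9 and 2 adjusted over the list alone). Histidine (4 of 6), aromatic (7 of 13, 1 lower) and other amino acid genes (12 of 24, 3 lower) were higher, with 4, 7 and 13 adjusted over the list alone. With an estimated correlation the adjusted p was 0.355 (proteasome), 0.718 (respiration), 0.688 (chaperones), 0.827 (synthetases), 0.325 (ergosterol), 0.712 (nitrogen and histidine), 0.732 (aromatic) and 0.694 (other), so none held, and with total RNA as the denominator the proteasome and respiration medians were 0.16 and 0.27 and the other 7 lists lost their calls (chaperones 0.00, ergosterol 0.06, nitrogen -0.19, histidine 0.06, aromatic 0.03, other 0.00), the synthetase median turning to -0.07. Arginine genes (median 0.01, mean -0.02) and sulfur genes (median -0.01, mean 0.06) were not called, nor were ribosomal protein (median -0.01) and biogenesis genes (median -0.04). The 3-prime minus 5-prime signal was 0.90 ± 0.05 in fed wild-type polysome and 1.62 ± 0.12 in non-polysome RNA.

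The next comparison asks which wild-type messages shift between the pools on starvation. The ratio of polysome to non-polysome signal changed at 2118 genes, upward at 1242 and downward at 876, a balance that turned in the MAS5 signals, with 1036 up and 1249 down without the mismatched columns and 464 up and 599 down as deposited. GCN4 rose 1.60-fold (0.68 ± 0.14) and CPA1 1.57-fold (0.65 ± 0.14), both messages with upstream reading frames. Of the 9 genes with such frames only these 2 passed (2 adjusted over the list alone), and the list, with a median of 0.15, was not called (adjusted p = 0.544; median -0.04 with total RNA as the denominator). HXT14, of the sugar transporter family, rose 4.81-fold (2.27 ± 0.34), PAU21 3.64-fold, NFT1 3.63-fold, VTH1, a sorting receptor, 2.99-fold, the kinase gene KNS1 2.98-fold and GIT1, a phospholipid metabolite transporter, 2.94-fold. HAC1 fell 8.62-fold (-3.11 ± 1.01), SRO9, an RNA-binding protein, 6.91-fold (-2.79 ± 0.47), SCS3 5.74-fold, the G1 repressor gene WHI5 4.97-fold, the pre-rRNA processing gene REX4 4.54-fold and the carboxypeptidase gene CPS1 4.43-fold. With total RNA as the denominator, a whole that holds the polysome pool, only 46 genes were called by limma. GCN4 then gave 0.18 (adjusted p = 0.603) and CPA1 0.06 (adjusted p = 0.886). NFT1 turned to -0.26, and VTH1, KNS1, GIT1, SCS3, CPS1 and HAC1 lost their calls. In the MAS5 signals GCN4 turned to -0.08 and CPA1 to -0.09. HAC1 also lost its call without wild-type fed polysome replicate 2 (-2.24, adjusted p = 0.114) or starved polysome replicate 2 (-2.46, adjusted p = 0.0867), and gave -3.98 and -3.76 without replicate 1 of each. WHI5 lost its call without each of 4 arrays in turn (adjusted p from 0.0591 to 0.124), with -1.72 without fed polysome replicate 2 and -2.90 without replicate 1, and SRO9 gave -3.44 and -2.13 without starved non-polysome replicate 1 and 2.

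Of 127 ribosomal protein genes 29 fell (11 adjusted over the list alone), median -0.34, RPL15A by 0.83 and RPS14B by 1.34. Of 66 mitochondrial ribosomal protein genes 25 fell and 4 rose (27 and 5 adjusted over the list alone), median -0.34, and of 118 biogenesis genes 26 fell and 1 rose (25 and 1 adjusted over the list alone), median -0.37, NOP58 by 1.33. Of 24 G1/S genes 13 rose and 2 fell (15 and 2 adjusted over the list alone), RNR1 by 1.07. Aromatic (8 of 13 down, 9 down and 1 up adjusted over the list alone) and other amino acid genes (10 of 24 down, 3 up, 11 and 5 adjusted over the list alone) were called downward. The adjusted p with an estimated correlation was 0.824 (ribosomal proteins), 0.712 (mitochondrial and G1/S), 0.906 (biogenesis), 0.690 (aromatic) and 0.697 (other), so none held, and with total RNA as the denominator the first 3 medians were -0.11, -0.08 and -0.20, while the other 3 lists lost their calls, with medians of 0.26 (G1/S, adjusted p = 0.108), 0.03 (aromatic, turned, adjusted p = 0.928) and -0.06 (other, adjusted p = 0.219). Arginine (median -0.26), sulfur (0.14), lysine, histidine and branched-chain genes (median 0.00, mean -0.09) were not called. The change followed gene length across genes (Spearman 0.43): of the 1329 longest genes 612 rose and 19 fell, and of the 1342 shortest 134 rose and 321 fell. After removal of that trend the medians were -0.17, -0.15 and -0.44. The 3-prime minus 5-prime signal went from 0.90 ± 0.05 to 1.29 ± 0.06 in polysome RNA and from 1.62 ± 0.12 to 1.56 ± 0.03 in non-polysome RNA.

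**Figure D4:**
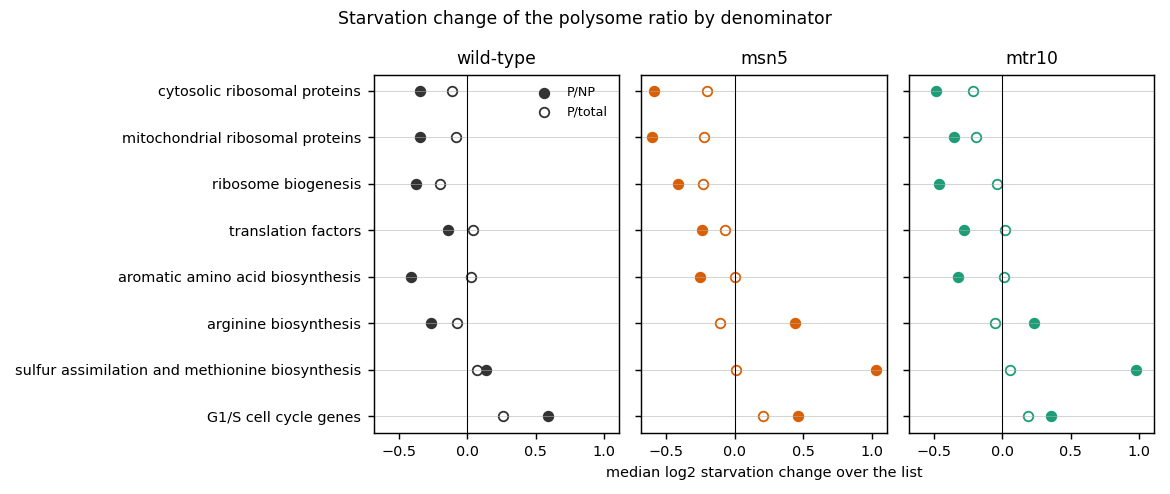
Median log2 change on starvation over each gene list of polysome against non-polysome RNA (filled) and polysome against total RNA (open), with a panel for each strain. Sulfur genes in msn5 lie at 1.03 against non-polysome RNA and at 0.01 against total RNA.

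In the mutants the same ratio changed at 2337 genes in msn5 (1345 up, 992 down) and 1731 in mtr10 (931 up, 800 down), while the MAS5 signals without the mismatched columns gave more falls than rises (1051 up and 1380 down, 592 up and 977 down), as did those as deposited (474 and 784, 152 and 302). The changes correlated with wild-type across genes at 0.88 and 0.82. GCN4 rose by 0.76 in msn5 and 0.50 in mtr10, and CPA1 by 0.97 and 0.63. MFA2 rose 6.65-fold and SEO1 6.42-fold in msn5, and SUL1 7.13-fold (2.83 ± 0.71), BDH2 5-fold and SEO1 4.11-fold in mtr10. REX4 fell 4.94-fold, ADA2 4.92-fold and SRO9 4.61-fold in msn5, and HAC1 8.14-fold, SRO9 7.98-fold and RPP2A 6.21-fold in mtr10. Of 27 sulfur genes 17 rose and 1 fell in msn5 (18 and 1 adjusted over the list alone), median 1.03, and 16 rose in mtr10 (19 adjusted over the list alone), median 0.98, MET1 by 2.08 and 1.71. The fed ends of these ratios are the non-polysome arrays on which the deleted genes read highest and starvation genes were high too: MFA2 and SEO1 read 9.35 and 9.72 there in msn5 against 7.49 and 7.57 in fed total RNA, and SUL1 10.77 in mtr10 against 8.24. Of 127 ribosomal protein genes 83 fell in msn5 (91 adjusted over the list alone) and 51 in mtr10 (58 adjusted over the list alone), and of 118 biogenesis genes 32 and 26 (29 and 24 adjusted over the list alone). Of 8 arginine genes 4 rose in msn5 (4 adjusted over the list alone), and of 13 aromatic genes 6 fell in mtr10 (6 adjusted over the list alone). No list held with an estimated correlation, where the adjusted p was 0.750 and 0.726 (sulfur), 0.718 and 0.750 (ribosomal proteins), 0.878 and 0.851 (biogenesis), 0.748 (arginine) and 0.750 (aromatic).

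With total RNA as the denominator 4 genes were called in msn5 and 5 in mtr10, and the sulfur medians were 0.01 and 0.06, those of ribosomal protein genes -0.20 and -0.21 and of biogenesis genes -0.23 and -0.04. The sulfur lists, the biogenesis list of mtr10 (adjusted p = 0.0533), the arginine list of msn5 (turned to -0.11) and the aromatic list of mtr10 (turned to 0.01) then lost their calls. GCN4 then gave 0.08 in msn5 and turned to -0.02 in mtr10, CPA1 gave 0.08 and turned to -0.09, STR3 turned to -0.23 in msn5, and BDH2 turned to -0.01 and MET13 to -0.15 in mtr10. SUL1 gave 0.32 and SEO1 0.35 in mtr10, MFA2 0.52 and SEO1 0.25 in msn5. In the MAS5 signals without the mismatched columns 2431 and 1569 genes were called (1258 and 454 as deposited), and GCN4 turned to -0.06 in both mutants and CPA1 to -0.08 in mtr10, while CPA1 lost its call in msn5 (adjusted p = 0.163); with only the compared groups in the fit 895 were called in msn5. In mtr10 HAC1 lost its call without each of 6 arrays in turn (adjusted p from 0.0552 to 0.1), GCN4 without fed polysome replicate 2 (adjusted p = 0.0663) or fed non-polysome replicate 2 (adjusted p = 0.0575), and the count was 1036 without that last array. Histidine genes of msn5 (median 0.13, mean -0.03) and branched-chain genes of mtr10 (median -0.02, mean 0.00) differed in sign.

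Between strains the fed ratio differed at 3 genes in msn5: CMK1, a calmodulin kinase gene (0.99 ± 0.16), STR3, of methionine synthesis (-2.64 ± 0.38), and the residual MSN5 signal (-2.60 ± 0.22). In mtr10 443 genes differed (226 higher, 217 lower; 85 and 159 in the MAS5 signals without the mismatched columns). The membrane sensor gene MTL1 (2.57-fold), the transcription factor gene YAP7 (2.40-fold) and KAP123, another nuclear carrier (2.36-fold), led upward, and SUL1 (7.06-fold), STR3 (5.52-fold) and BDH2 (4.83-fold) downward. The SUL1 value of -2.82 lost its call without wild-type fed non-polysome replicate 1 (-1.97, adjusted p = 0.108) or wild-type fed polysome replicate 2 (-2.23, adjusted p = 0.105) and gave -3.67 and -3.41 without the other array of each. Of 27 sulfur genes 1 was lower in msn5 (15 adjusted over the list alone), median -0.60, and 13 were lower and 1 higher in mtr10 (17 and 1 adjusted over the list alone), median -0.88, MET17 with -0.85 and MET2 with -1.81. Of 8 arginine genes 0 passed in msn5 (5 lower adjusted over the list alone) and 3 were lower and 1 higher in mtr10 (4 and 1 adjusted over the list alone). In mtr10 5 of 20 synthetase genes (9 adjusted over the list alone), CDC60 with 1.02, and 5 of 118 biogenesis genes (0 adjusted over the list alone), LSG1 with 0.83, were higher. With an estimated correlation the adjusted p was 0.250 and 0.650 (sulfur), 0.0765 and 0.737 (arginine), 0.688 (synthetases) and 0.842 (biogenesis), so none held.

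With total RNA as the denominator limma called 0 genes in both fed comparisons, with 34 and 468 at an unadjusted p under 0.05. The sulfur medians were then 0.05 and 0.04, the arginine medians 0.02 and -0.01, and in mtr10 the synthetase list kept its call (median 0.13, adjusted p = 0.999 with an estimated correlation) and the biogenesis list lost it (median 0.15). STR3 turned to 0.01 in msn5, and BDH2 turned to 0.06 and MET17 to 0.21 in mtr10. These comparisons too rest on the fed non-polysome arrays on which the deleted genes read highest, where the 3-prime minus 5-prime signal was 1.93 ± 0.25 in msn5 and 2.21 ± 0.09 in mtr10 against 1.62 ± 0.12 in wild-type. CMK1 lost its call without wild-type fed polysome replicate 2 (adjusted p = 0.0676), wild-type fed non-polysome replicate 2 or msn5 fed polysome replicate 1 (0.0516 each), and the mtr10 count ranged from 135 without mtr10 fed polysome replicate 1 to 514 without mtr10 fed non-polysome replicate 2, and was 244 in the MAS5 signals without the mismatched columns. GCN4 (0.01 and 0.07) and CPA1 (-0.32 and 0.10) did not pass in either (adjusted p from 0.688 to 1).

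After starvation 4 genes differed in this ratio in msn5, CMK1 (0.82), ECM23 (-1.72), SPS4 (-1.17) and IOC2 (-0.65), and 97 in mtr10 (42 higher, 55 lower). MRX3 (2.20-fold), SSA1 (2.11-fold) and IMA3 (2.09-fold) led upward in mtr10 and AAD14 (3.77-fold), RPP2A (3.16-fold) and AMS1 (2.26-fold) downward. Of 26 chaperone genes 3 were higher in mtr10 (10 adjusted over the list alone; adjusted p = 0.355 with an estimated correlation), and of 127 ribosomal protein genes 3 were lower (3 adjusted over the list alone; adjusted p = 0.934 with an estimated correlation). Ribosomal protein genes of msn5 had a median of -0.17 with 0 genes called (0 adjusted over the list alone; adjusted p = 0.827 with an estimated correlation). With only the compared groups in the fit limma called 0 genes in either mutant (99 and 715 at an unadjusted p under 0.05), with total RNA as the denominator 0 (181) and 39, and SSA1 turned to -0.13, while the chaperone list of mtr10 lost its call (median 0.04). Single arrays moved the msn5 count between 0 (without wild-type starved non-polysome replicate 2, with 267 at an unadjusted p under 0.05) and 93 (without msn5 starved polysome replicate 1), and the mtr10 count to 24 (without wild-type starved polysome replicate 1); in the MAS5 signals without the mismatched columns the latter was 25. The 3-prime minus 5-prime signal of starved non-polysome RNA was 1.86 ± 0.09 in msn5 and 2.14 ± 0.09 in mtr10 against 1.56 ± 0.03 in wild-type, and that of starved polysome RNA 1.26 ± 0.28 and 1.63 ± 0.13 against 1.29 ± 0.06.

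The last test asks whether starvation shifts messages between the pools differently in a mutant. In msn5 1 gene passed, the residual MSN5 signal, which was not detected in starved polysome or total RNA of that strain, so its difference has no reliable size, and which lost its call with only the compared groups in the fit (adjusted p = 0.0787). In mtr10 limma called 0 genes, with 433 at an unadjusted p under 0.05, and between 0 and 7 under the alternatives. GCN4 gave 0.09 in msn5 and -0.18 in mtr10, and CPA1 0.32 and -0.02 (adjusted p from 0.910 to 1). The sulfur list was called in both, with medians of 0.70 and 0.95 and 0 genes (7 and 2 adjusted over the list alone), as was the arginine list, with medians of 0.54 and 0.39 and 0 genes (5 and 3 adjusted over the list alone). With an estimated correlation the adjusted p was 0.325 and 0.604 (sulfur) and 0.178 and 0.697 (arginine), and with total RNA as the denominator the sulfur medians, which then use no non-polysome array, were -0.07 and 0.00 and the arginine medians turned to -0.02 and -0.04, with neither list called (adjusted p from 0.853 to 0.992). In simulated data with the same groups this test recovered 56% of genes that differed by 1 on the log2 scale and 4% of those that differed by 0.5. Over all 19 comparisons 219 of 646 list tests were called, 6 of them with an estimated correlation.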

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

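The comparisons between strains were planned, and all the tests of explanations in this part were chosen only after the result was seen.

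The test of the difference itself found 37 genes whose response of total RNA to starvation differed between msn5 and wild-type and 763 between mtr10 and wild-type. The difference of the starvation change of the polysome to non-polysome ratio between msn5 and wild-type passed for 1 gene, the residual MSN5 signal, which was not detected in part of these groups. Probe sets for exogenous poly(A) control RNA, which enter no comparison, read 12.92 ± 0.16 in non-polysome RNA and 10.03 ± 0.67 in polysome RNA against 4 ± 0.14 in total RNA (mean ± SD of 12 arrays each). In polysome RNA they went from 10.61 ± 0.20 fed to 9.45 ± 0.35 starved, and in non-polysome RNA from 12.91 ± 0.15 to 12.93 ± 0.18 (6 arrays each).

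Sulfur and methionine genes were called toward a lower polysome to non-polysome ratio in both fed mutants, with 1 of 27 lower in msn5 (15 adjusted over the list alone) and 13 lower and 1 higher in mtr10 (17 and 1 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.250 and 0.650). In msn5 a change of these genes alone is argued against by 29 other genes that starvation raises 8-fold or more, with a median excess of 0.58 ± 0.20 on the fed non-polysome arrays (the error is from replicate arrays, as in the medians that follow), while in mtr10 0.34 ± 0.20 leaves it open. RNA of starved cells that hold the deleted gene is a candidate source. On those arrays MSN5 and MTR10 exceeded their levels on the other 10 arrays of the strain by 2.90 and 1.25 (log2). MTR10 was not detected in any other mtr10 group, nor MSN5 in starved polysome or total RNA of msn5, so these differences have no exact size. PHO84 too read 10.92 on 1 of these mtr10 arrays (7.74 on the other). With wild-type levels assumed for RNA of that source, the share it needs, 4.4% in msn5 and 2.1% in mtr10, would raise the list by 0.34 and 0.15 against 0.80 and 0.94 ± 0.33 measured, so whether it accounts for the whole pattern stays open. Derepression would raise the list in fed total RNA. Its median there was -0.53 ± 0.23 in msn5 and -0.29 ± 0.23 in mtr10. The pooled error may be too small, since fed wild-type replicates differed (MET3 10.26 and 11.41, STR3 9.72 and 10.75). No rise of the median was seen, but derepression stays open. SUL1 was higher (8.03 in msn5, 6.82 in wild-type). Fewer ribosomes on these messages cannot be told apart from carried-over RNA, since the list's median in the polysome to total ratio of msn5 was 0.05 ± 0.33.

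In starved wild-type the MATa-specific genes rose in a MATalpha strain. RNA of another sample of the series is argued against by levels that lie 0.77 ± 0.26 above the highest group of another strain (median of the 7 genes), with 6 of 7 above it and MFA1 as the exception (12.55 against 12.88 in starved mtr10 non-polysome RNA). A fall of the message of the alpha2 repressor, which holds these genes off, is argued against by the HMRA2 probe set, which shares sequence with that gene and changed by 0.14 ± 0.11. MATa cells in the starved cultures cannot be told apart from a change within the cells, since the MATalpha-specific genes they would lower went both ways: STE3 rose by 0.41 ± 0.10, MF(ALPHA)2 fell by 1.26 ± 0.19, and 3 others were not called (median of all 5 -0.13). Loss of the repressor protein may underlie the rise too, a hypothesis that arrays cannot test.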

How the results depend on the processing

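The alternatives with the MAS5 signals without 2 columns and with crossed replicate numbers were added after the data were seen; all others were planned. The cause of a change was not tested unless it is named. Leaving out each array in turn leaves 1 array in a group, whose spread is assumed to be like that of the other groups. No called gene that the text names reversed then. Of the named values 2325 kept their side of the threshold, 167 lost their call and 8 gained one. The direction was compared for called values only. The counts then ran from 2858 to 3119 (wild-type starvation, total RNA), 2606 to 2857 (msn5), 2044 to 2138 (mtr10), 238 to 346 (msn5 fed), 1384 to 1516 (mtr10 fed), 417 to 954 (msn5 starved), 2227 to 2516 (mtr10 starved), 15 to 57 and 443 to 665 (differences of the response, msn5 and mtr10), 2106 to 2284 (polysome against non-polysome), 1614 to 1959, 1707 to 2497 and 1036 to 1782 (ratio change in wild-type, msn5 and mtr10), 2 to 7 and 135 to 514 (fed ratio, msn5 and mtr10), 0 to 93 and 24 to 91 (starved ratio), 1 to 3 and 0 to 1 (differences of the ratio change), 67 to 187 (shared by both fed mutants) and 209 to 235 (list calls).

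Centring the arrays kept 424 of 429 named values, no detection filter 429, genes Present on all arrays 372 with 3 losing their call, and trend and robust settings 427, with none reversed. Genes Present on all arrays gave 1 call in the starved ratio of msn5 and 0 by limma in the difference of the ratio change between msn5 and wild-type (137 at an unadjusted p under 0.05). Trend and robust settings gave 7 in that difference for mtr10. With only the compared groups in the fit, which leaves fewer arrays to estimate the spread, the counts were 1530 (msn5 fed, 711 higher and 819 lower), 319 (msn5 starved), 7 (difference of the response of msn5), 895 (ratio change in msn5), 0 by limma for the starved ratios of both mutants (99 and 715 at an unadjusted p under 0.05), and 0 (107 at an unadjusted p under 0.05) and 1 for the differences of the ratio change. Replicate numbers did not pair the samples throughout: deviations from the group mean on arrays of the same strain, condition and number correlated across genes with a median of 0.44 over 18 pairs (from -0.66 to 0.64, 13 above 0.1). A block for the number gave 90 calls in the difference of the response between msn5 and wild-type, and changed no other count of the total RNA responses by over 1.5 times, no other named gene there than the 3 given and none of their list calls. It gave 6 in the fed ratio of msn5, 173 in the starved ratio of mtr10 and 2 in the difference of the ratio change between mtr10 and wild-type, and crossed numbers of fed msn5 polysome RNA gave 17 in the fed ratio of msn5. Camera with an estimated correlation called 6 of 646 list tests. All MAS5 results that follow, those as deposited included, are after each array was centred on its log2 median, and no fit without that step was run.

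As deposited, the MAS5 signals gave 0 calls by limma for wild-type starvation (27 at an unadjusted p under 0.05), 1683 for mtr10, 364 and 703 for msn5 fed and starved, 1623 for mtr10 starved, 94 for the difference of the response of mtr10, 1063, 1258 and 454 for the ratio changes, 0 (86 at an unadjusted p under 0.05) and 21 for the fed ratios, 0 (136 at an unadjusted p under 0.05) and 1 for the starved ratios, 0 (47 at an unadjusted p under 0.05) for the ratio change of msn5 against wild-type, and 135 shared genes. Without the 2 mismatched columns they gave 342 and 433 for msn5 fed and starved, 10 and 264 for the differences of the response, 2285, 2431 and 1569 for the ratio changes, 6 and 244 for the fed ratios, 25 for the starved ratio of mtr10, 0 (137 at an unadjusted p under 0.05) and 1 for the differences of the ratio change, and 112 shared genes. The balance of directions turned there in the starvation response of mtr10 (1301 up, 1464 down), fed and starved mtr10, the 3 ratio changes and the fed ratio of mtr10, and with centred arrays in the ratio change (831 up, 855 down) and the fed ratio (206 and 241) of mtr10 and in fed mtr10 (1052 and 1049). With the mismatched columns 82 named values reversed. In wild-type starvation these were SUL1 -1.14, SEO1 -0.51, MFA2 -0.06, AGA2 -0.65, STE2 -0.17, CRC1 -0.067, URA1 0.14, LTV1 0.89, NIP7 0.42, MSN5 -0.11, MET16 -0.32, MET1 -0.22, MET13 -0.058, LYS14 -0.023, LEU9 0.00, DUR3 -0.094, PUT1 -0.024, DAL7 -0.023, RPP1 0.14 and RPS22B 0.025. They went on with RPL8A 0.15, RRP15 0.17, MPP10 0.26, DIM1 0.21, LSG1 0.14, RPC31 0.22, RPC34 0.24, RPA43 0.49, RPA34 0.23, TIF5 0.14, TIF35 0.20, CDC33 0.083, TEF4 0.079, HSC82 0.013, SSA1 0.017, GLC3 -0.13, ALD3 -0.36, PRE5 0.01, RPN11 0.01, PUP2 0.013, ASG7 -0.30, BAR1 -0.076, MFA1 -0.047, SRM1 0.15, SEN34 0.043, YRB1 0.056 and TRZ1 0.025. Other reversals were BAR1 -0.48 in fed mtr10, and BAR1 0.11, ASG7 0.46, MFA1 0.82, AGA2 1.16 and HSC82 -0.38 in starved msn5. In the difference of the msn5 response SSA1 gave -1.16, RIO1 -0.56, BAR1 2.08 and AHA1 -0.67. In that of the mtr10 response HO gave -0.81, SSA1 -0.40, AGA2 1.20, MFA2 1.02, ASG7 0.21, MFA1 0.42, BAR1 1.11, CPR6 -0.83, HSC82 -0.78, SSA2 -0.93, RPT2 -0.006, RPT1 -0.37, RPT4 -0.15, RPN11 -0.61, ARG1 0.21, ARG7 1.73, ARG3 2.62 and ARG8 1.22. These groups hold the 2 columns that match the other condition. Without them the 8 reversals left were GCN4 on starvation (-0.19 in wild-type, -0.20 in msn5, -0.052 in mtr10, the last 2 also with the columns), GCN4 in the ratio change (-0.080, -0.057 and -0.063) and CPA1 there (-0.093 in wild-type and -0.078 in mtr10), as with the columns, and 48 values lost their call.

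With total RNA as the denominator the counts were 670 (polysome against the other pool in wild-type), 46, 4 and 5 (ratio changes in wild-type, msn5 and mtr10), 0 and 0 by limma (fed ratios, 34 and 468 at an unadjusted p under 0.05), 0 and 39 (starved ratios, 181 at an unadjusted p under 0.05 for msn5) and 0 (ratio change of msn5 against wild-type, 19 at an unadjusted p under 0.05). Of the named values 53 kept their call or lack of one, 90 lost it and 17 reversed. That ratio sets a part against the whole, so a lost call alone does not decide against the ratio of the pools. The reversals were DAN4 -0.52, FLO11 -0.49 and, for FIG2, a value of -0.751 in fed wild-type, NFT1 -0.26 in the wild-type ratio change, MSN5 -0.14 and STR3 -0.23 in that of msn5, and BDH2 -0.006, MTR10 -0.64, GCN4 -0.015, CPA1 -0.085 and MET13 -0.15 in that of mtr10. In the fed ratio they were STR3 0.007 and MSN5 0.56 (msn5) and BDH2 0.062 and MET17 0.21 (mtr10), in the starved ratio SSA1 -0.13 (mtr10), and in the difference of the ratio change MSN5 -0.38 (msn5). The signs of MSN5 and MTR10 carry no weight, since neither was detected in total RNA of its deletion strain. Signal over background limits the deleted genes and other dim values, whose folds are lower bounds.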

Other observations

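The comparisons here were planned, and the tests of explanations at the end were chosen only after the result was seen. Further groups of genes moved on starvation in total RNA of the mutants. Of 22 genes under nitrogen catabolite repression 17 rose and 3 fell in msn5 (17 and 4 adjusted over the list alone) and 18 rose in mtr10 (18 up and 1 down adjusted over the list alone), and of 41 general stress genes 30 rose and 1 fell in msn5 (30 and 1 adjusted over the list alone) and 28 rose in mtr10 (29 adjusted over the list alone). All but 2 of the 19 RNA polymerase I and III genes fell in msn5 and all 19 in mtr10 (18 and 19 adjusted over the list alone), and 31 and 30 of 33 translation factor genes fell (31 and 30 adjusted over the list alone). Genes of tRNA processing and nuclear transport, the process the deleted carriers serve, fell for 15 and 14 of 22 (15 and 15 adjusted over the list alone). With an estimated correlation the adjusted p was 0.355 and 0.178 (nitrogen), 0.741 and 0.729 (stress), 0.697 and 0.572 (polymerases), 0.355 and 0.280 (factors) and 0.355 and 0.356 (tRNA). Gene length was related to the ratios in the mutants too: the ratio change on starvation correlated with gene length across genes at 0.48 in msn5 and 0.38 in mtr10, and the fed ratio of mtr10 against wild-type at 0.43.

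Some groups were not called in starved wild-type total RNA. Of 15 amino acid permease genes 9 rose and 2 fell (9 and 2 adjusted over the list alone), with an adjusted p of 0.0634, and of 7 calcineurin targets 5 rose (5 adjusted over the list alone). Of 9 genes with upstream reading frames 3 rose and 4 fell (3 and 4 adjusted over the list alone), and of 16 glycolysis genes 7 fell (6 adjusted over the list alone), with an adjusted p of 0.0753. Of 23 ergosterol genes 11 fell and 3 rose (11 and 3 adjusted over the list alone), of 14 pheromone genes 8 rose and 3 fell (8 and 3 adjusted over the list alone), and of 9 genes of the unfolded protein response 5 fell and 1 rose (5 and 1 adjusted over the list alone).

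Of 127 ribosomal protein genes 29 fell in the polysome to non-polysome ratio after starvation in wild-type (11 adjusted over the list alone), and the list's call was lost with an estimated correlation (adjusted p = 0.824). Its median of -0.34 is within 2 errors of 0 (error 0.19 from replicate arrays), while -0.59 in msn5 and -0.48 in mtr10 are beyond, and after the trend with gene length was removed the medians were -0.17, -0.41 and -0.31 ± 0.17, the msn5 value -0.12 without msn5 starved polysome replicate 2, so length cannot be told apart from a change of these messages. With total RNA as the denominator wild-type gave -0.11 ± 0.19, and -0.09 ± 0.17 without the length trend, which leaves the denominator, and both together, open too. Against total RNA, where changes were smaller, limma called 0 of the 127 genes lower (4 at an unadjusted p under 0.05) and the list stayed called with the preset correlation (adjusted p = 4.22e-05; 7.64e-12 in msn5 and 2.65e-14 in mtr10, medians -0.20 and -0.21) but not with an estimated one (adjusted p = 0.999 in each). RNA breakage stays open as well: the 3-prime minus 5-prime signal rose by 0.45 ± 0.10 more in polysome than in non-polysome RNA (0.27 ± 0.28 in msn5, 0.56 ± 0.15 in mtr10), and across 18 pairs of replicate arrays the list's median went up with that signal (slope 0.52 ± 0.23), which would give a rise of 0.23 ± 0.10 and no fall, but the slope rests on 1 pair (0.19 ± 0.24 without starved msn5 polysome RNA).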
